A study of Mus musculus with 9 samples.

How the data were processed

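RNA was taken from mouse pancreatic tumor cells and sequenced by a commercial provider, per the labels' protocols, in 9 libraries: 3 of parental cells, 3 of escape e1 and 3 of escape e2. Per the labels, groups and library numbers come from the sample titles. The authors deposited a table of TPM per gene and library and a table of log2 values, the rlog transform. Salmon and DESeq2 and the mm10 genome build are named per the submitters' processing notes, and their versions, the annotation, strand setting and aligner options are not given in the sources used here. TPM, as the authors deposited it, has a fixed sum per library and keeps no read depth, so no counting interval or detection limit can be given. A gene at 0 is described only as listed at 0. In the deposited TPM table a single small RNA gene, Mir6236, held 3.92 to 9.48% of the total, and no mitochondrially encoded gene was present.

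The analysis began from log2(TPM + 1) values. Genes at 1 TPM or more in at least 3 of the 9 libraries were kept, 12769 of 24493. A linear model with 3 group means was fitted in limma 3.58.1 under R 4.3.3, with a mean-variance trend and robust empirical Bayes, and contrasts gave e1 minus parental, e2 minus parental, e2 minus e1 and the mean of e1 and e2 minus parental. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Gene lists fixed before the data were examined, 37 in number, were compared with other genes by limma's camera at a preset correlation of 0.01 where at least 5 genes were tested, which held for 30 lists, and again with a correlation estimated from the data. For lists fixed in advance with fewer tested genes only values are given, while gene families chosen later were tested from 3 genes on. Some lists share genes, so called lists are not all separate findings.

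Named genes follow a rule fixed before the data were examined. Per comparison it takes the 8 genes highest and 8 lowest in fold change among called genes with a mean of at least 10 TPM in the higher group and libraries that do not overlap, leaving out predicted and clone-named genes, pseudogenes and mitochondrial transcripts. Per list and comparison it takes up to 2 called members in each direction. It adds 40 genes named whatever their result, and the 6 highest and 6 lowest genes called alike in both lines. The text names fewer genes than the rule gives. Genes named outside it include Ifitm2 and Ifitm10, of a family chosen after the data were seen. Others serve only for checks, such as Pdx1, Lum and Mir6236. Coordinates are from a RefSeq gene table of the mouse assembly GRCm38.p6, matched by symbol for 23851 of 24493 genes and by synonym for 550, with 87 unmatched and 5 ambiguous.

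The shared parental libraries raise agreement between the lines by chance. To gauge this, all 9 libraries were drawn 100 times around the parental means, with both lines unchanged. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-ratio scaling, removal of the 10 highest genes with rescaling, the rlog table, fits of the compared groups only, the library number as a block, an empirical Bayes fit without trend and robustness, and leaving out each library in turn. Chromosome medians, 8 further gene families, their rerun with no filter and the tests of e1 library 1 were chosen after the data were seen.

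The steps were tested on simulated data in which 200 genes were changed. Of genes changed by 0.5, 1 and 2 on the log2 scale, 53 of 67, 65 of 67 and 66 of 66 were recovered for e1 against parental (11922 genes in the step), 57 of 67, 67 of 67 and 66 of 66 for e2 against parental (11903 genes), and 57 of 67, 65 of 67 and 66 of 66 for e2 against e1 (11914 genes). Of unchanged genes, 62 of 11024, 223 of 11005 and 35 of 11019 were called (0.562, 2.03 and 0.318%). These are shares of unchanged genes, and the share of false calls among all calls was larger. Besides the 200 changed genes, the simulated data held a shifted gene list and a shifted chromosome. False calls numbered 62 for e1 and 223 for e2 against parental. Even if every altered gene was called, their share of all calls exceeded the adjusted p threshold in both, and more so for e2. Few genes were changed in the simulation, whereas most tested genes passed in the data, so these shares do not carry over to the data. A chromosome whose genes were shifted by 0.5 was found at 0.494, 0.488 and 0.490 in the same order. Among gene names of the rlog values, 26 read as dates.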

Results

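Gene expression was profiled by RNA sequencing in mouse pancreatic tumor cells on a C57BL/6 background, grown in DMEM with serum and given no treatment. There were 9 libraries in 3 groups of 3: the parental cells and the derived lines escape e1 and escape e2, which the series describes as resistant to immunotherapy. Expression is given as TPM, a transcript abundance relative to the library total. It keeps no sequencing depth, so the depth of each library is unknown. Between 11188 and 12039 genes stood at 1 TPM or more per library, and 12769 genes were tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values here measure only the spread between these libraries. Values are mean TPM ± SD over n = 3 libraries, and log2 fold changes on the log2(TPM + 1) scale ± SE, which understate the change of genes near 0. Adjusted p-values are from limma unless a gene list is named, where they are from its camera test. Pearson correlations of log2 values over genes ran from 0.987 to 0.995 within groups, from 0.840 to 0.863 between parental and escape libraries, and from 0.910 to 0.923 between e1 and e2 libraries.

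The comparison of escape e1 with the parental cells asks how the first resistant line differs from the cells it came from. Epithelial genes fell in e1 and mesenchymal genes rose. Krt7, a keratin of ductal epithelium on chromosome 15 (101412403 to 101427806), fell from 2264 ± 163 TPM in parental cells to 1.05 ± 0.182 TPM in e1, a log2 fold change of -10.11 ± 0.08 with an adjusted p of 2.9e-12. Epcam, a surface adhesion protein of epithelial cells, fell from 133 ± 32.8 to 0.296 ± 0.0427 TPM, and Cdh1, which encodes E-cadherin, from 227 ± 4.92 to 9.56 ± 2.58 TPM. Of the 35 epithelial genes tested, 34 were lower and 1 was higher, with the same counts when adjusted over the list alone, and the median log2 fold change was -4.32 (adjusted p = 1.05e-16; adjusted p = 0.0305 with an estimated correlation). The exception was Jup, a junction protein shared by desmosomes and adherens junctions, at 0.44 ± 0.10. The tight junction gene Cldn4 had a log2 fold change of -7.56 ± 0.17, Cldn7 of -6.92 ± 0.07, and Muc1, a membrane mucin, of -7.03 ± 0.07.

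Of the 33 mesenchymal genes tested in e1, 28 were higher and 0 lower, also when adjusted over the list alone (median 2.29, adjusted p = 1.43e-10; adjusted p = 0.014 with an estimated correlation). Vim, the intermediate filament vimentin, rose from 804 ± 199.5 to 3524 ± 215 TPM, and Acta2, smooth muscle actin, from 0.0577 ± 0.0337 to 263 ± 82.6 TPM (7.92 ± 0.17 on the log2 scale). Sparc, a matrix glycoprotein, rose by 5.12 ± 0.15, the repressor of epithelial genes Zeb1 by 1.18 ± 0.09, and Fstl1, a secreted glycoprotein, by 7.06 ± 0.15. Of 14 fibroblast marker genes, 10 were higher and 0 lower, also when adjusted over the list alone (median 1.68, adjusted p = 0.00198, and 0.106 with an estimated correlation). In parental cells only 1 of 16 markers, Fbln1, had a mean of 1 TPM or more. The other tested markers entered through escape libraries and could hardly come out lower, so these counts were largely set by the filter. The filter removed none of the 33 mesenchymal genes. Still, mesenchymal and matrix genes near 0 in parental cells, such as Acta2 and Col1a1, could hardly come out lower either. Among the markers, Col1a1 rose from 0.432 ± 0.0967 to 103 ± 25.2 TPM. Col1a2 was listed at 0 in all 3 parental libraries and stood at 108, 119.9 and 119 TPM in the e1 libraries, while Dcn, the proteoglycan decorin, stood at 0.127, 0.227 and 0.0897 TPM there. In the extracellular matrix list, 21 of 31 genes were higher and 6 lower (22 and 6 adjusted over the list alone; median 1.07, adjusted p = 0.00198; adjusted p = 0.197 with an estimated correlation). The lower members included the laminin subunit gene Lamb3, at -5.14 ± 0.18, while the thrombospondin gene Thbs1 rose by 1.78 ± 0.19. Thbs1 and Sparc are also in the mesenchymal list, and Col1a1, Col1a2 and Dcn are also fibroblast markers, so these calls overlap.

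Genes of the classical pancreatic cancer subtype fell in e1: 20 of 21 were lower and 1 higher, also when adjusted over the list alone (median -2.84, adjusted p = 8.77e-09; adjusted p = 0.0279 with an estimated correlation). Gata6, a transcription factor of this subtype, fell from 19.8 ± 2.18 to 0.142 ± 0.0355 TPM, and Lgals4, a galectin of gut and pancreatic epithelium, from 714 ± 271 to 1.16 ± 0.604 TPM. Ctse, which encodes cathepsin E, had a log2 fold change of -6.18 ± 0.08. Sox9, a transcription factor of pancreatic ducts, was the member that rose, at 1.43 ± 0.18. The basal-like subtype list was lower too: 12 of 17 genes were lower and 4 higher, also when adjusted over the list alone (median -1.39, adjusted p = 0.015; adjusted p = 0.136 with an estimated correlation). Among all genes, the highest fold changes included Ifitm3, at 9.11 ± 0.10, and Ifitm1, at 8.15 ± 0.20, interferon-induced membrane proteins of one family. In parental cells their relative Ifitm2 had a mean of 144 TPM, while Ifitm1 had 0.0789 TPM and Ifitm3 0.0854 TPM. These values argue against reads of Ifitm2 being counted for Ifitm1 or Ifitm3 there. The split of reads between Ifitm1 and Ifitm3 was not tested. Crabp2, a retinoic acid binding protein, rose from 0.173 ± 0.0200 to 147 ± 37.5 TPM. Mgp, a matrix protein that limits calcification, was listed at 0 in all 3 parental libraries and stood at 86.5, 117 and 114 TPM in e1.

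Genes of immune recognition moved in both directions in e1. B2m on chromosome 2 (122147687 to 122153082), the light chain of MHC class I, rose from 192 ± 12.6 to 699 ± 115 TPM (1.85 ± 0.10, adjusted p = 1.61e-07), while H2-K1 on chromosome 17 (33996012 to 34000619), a class I heavy chain, fell from 145 ± 8.27 to 28.1 ± 17.8 TPM (-2.49 ± 0.34, adjusted p = 0.000309). The other heavy chain gene H2-D1 stood at 130.5 ± 23.3 TPM against 100.5 ± 8.17 TPM (0.36 ± 0.11). That call ended without parental library 1 (0.30, adjusted p = 0.0641), and the value was 0.22 without e1 library 1. Of 21 class I presentation genes, 14 were higher and 1 lower, also when adjusted over the list alone (median 0.45, adjusted p = 0.0164; adjusted p = 0.53 with an estimated correlation). The proteasome activator gene Psme2 rose from 79.7 ± 5.73 to 227 ± 11.6 TPM, the peptide transporter gene Tap1 by 0.83 ± 0.14 and the immunoproteasome subunit gene Psmb8 by 1.80 ± 0.36. Reads of class I heavy chain genes can be split among near-identical members, so their single values are uncertain.

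Of 34 type I interferon response genes, 21 were higher and 3 lower in e1, also when adjusted over the list alone (median 0.87, adjusted p = 0.00133; adjusted p = 0.711 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, rose from 1.08 ± 0.129 to 41 ± 22.1 TPM. Ifit1, an antiviral RNA-binding protein, rose from 0.0786 ± 0.0487 to 13.4 ± 7.42 TPM, and Mb21d1, the DNA sensor cGAS, from 0.326 ± 0.0501 to 10.5 ± 1.86 TPM. The exonuclease gene Isg20 fell by 1.62 ± 0.12. In 28 of these 34 genes e1 library 1 lay above both other e1 libraries. The interferon gamma list did not pass (13 of 22 higher and 6 lower, also when adjusted over the list alone; median 0.36, adjusted p = 0.145), but passed with no filter (0.04998; 0.04998 to 0.164 over the alternatives). Within it, Jak2, a kinase of the receptor, fell from 52.1 ± 2.25 to 8.86 ± 1.66 TPM and the receptor gene Ifngr1 from 95.7 ± 6.45 to 43.9 ± 2.84 TPM. The transcription factor gene Irf1 rose from 15.5 ± 1.17 to 52.4 ± 1.41 TPM.

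The list of checkpoint ligands and inhibitory surface molecules was lower in e1, with 10 of 16 genes lower and 2 higher, also when adjusted over the list alone (median -0.60, adjusted p = 0.015; adjusted p = 0.147 with an estimated correlation). Cd24a, a sialoglycoprotein, fell from 199 ± 5.02 to 26.9 ± 6.98 TPM, the adhesion molecule gene Ceacam1 had a log2 fold change of -3.01 ± 0.09 and the arginase gene Arg1 of -2.49 ± 0.08. Cd274, which encodes PD-L1, fell from 1.68 ± 0.265 to 0.681 ± 0.188 TPM (-0.67 ± 0.11), while Cd47, the ligand that restrains phagocytosis, stood at 46.3 ± 7.43 TPM against 53.7 ± 3.75 TPM and did not pass (-0.22 ± 0.11, adjusted p = 0.0933). It passed without e1 library 2, at -0.30 (adjusted p = 0.04), with median-ratio scaling (0.0437) and with the rlog values (0.043). Chemokine genes split by member. The neutrophil and myeloid list was not called (11 of 27 higher and 12 lower, also when adjusted over the list alone; adjusted p = 0.886), nor was that of T cell chemoattractants (3 of 5 higher and 1 lower, also when adjusted over the list alone; adjusted p = 0.742). Ccl2, which attracts monocytes, rose from 0.557 ± 0.177 to 34.1 ± 6.15 TPM, and the T cell chemoattractant gene Ccl5 from 0.0679 ± 0.118 to 21.2 ± 11.4 TPM. Cxcl5, which attracts neutrophils, fell from 67.2 ± 23.2 to 1.08 ± 0.417 TPM, and the colony-stimulating factor gene Csf2 from 12.2 ± 1.31 to 0.42 ± 0.113 TPM. The death receptor gene Fas rose by 1.02 ± 0.17, whereas the initiator caspase gene Casp8 fell by 0.89 ± 0.08. The survival gene Bcl2l1 fell by 1.52 ± 0.06, the adhesion ligand gene Icam1 by 2.38 ± 0.10 and the NKG2D ligand gene Raet1d by 2.76 ± 0.12.

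Cholesterol synthesis genes fell in e1, with 19 of 23 lower and 0 higher, also when adjusted over the list alone (median -0.75, adjusted p = 7.64e-05; adjusted p = 0.675 with an estimated correlation). Insig1, which holds back sterol regulation, fell from 176 ± 16.2 to 47.5 ± 2.81 TPM. In 22 of these 23 genes e1 library 1 lay above both other e1 libraries. Of 34 cell cycle genes, 21 were higher and 5 lower, also when adjusted over the list alone (median 0.27, adjusted p = 0.015; adjusted p = 0.711 with an estimated correlation). Cyclin gene Ccne2 rose by 1.07 ± 0.08, and the proliferation marker Mki67, at 0.07 ± 0.06, did not pass (adjusted p = 0.363). Myc rose from 161 ± 10.2 to 459 ± 77.6 TPM, Trp53 by 0.87 ± 0.07, the cell cycle inhibitor gene Cdkn2a by 0.89 ± 0.05 and the deubiquitinase gene Usp22 by 0.68 ± 0.08. The MYC and ribosome biogenesis list did not pass (13 of 26 higher and 2 lower, 13 and 1 adjusted over the list alone; median 0.30, adjusted p = 0.158). It passed without e1 library 2 and without e1 library 3, and its adjusted p ran from 0.0489 to 0.64 over the alternatives. Epha2, a receptor kinase, Pvr, a ligand of NK and T cell receptors, and the granzyme inhibitor gene Serpinb9 did not pass (-0.23 ± 0.13, 0.18 ± 0.28 and 0.37 ± 0.22), and each passed without e1 library 1, at -0.41, -0.21 and 0.68.

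In all, 9014 of 12769 genes passed in e1 at an adjusted p under 0.05 (9263 at an unadjusted p), 4560 higher and 4454 lower, of which 1010 and 1568 changed by at least 1 on the log2 scale. The share of higher calls was 50.6%, and from 47.7 to 51.9% over the alternatives. The 3 e1 and the 3 parental libraries did not overlap in 71.4% of genes, where chance gives 10%. Of 30 lists, 11 were called, 6 up and 5 down, and 3 held with an estimated correlation. The p53 target list was not called (11 of 23 genes higher and 9 lower, also when adjusted over the list alone; adjusted p = 0.829), nor were NF-kB targets (8 of 22 higher and 10 lower, also when adjusted over the list alone; adjusted p = 0.886). TGF-beta targets were not called either (9 of 23 higher and 12 lower, also when adjusted over the list alone; adjusted p = 0.819), with a median of -0.14 and a mean of 0.03.

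**Figure D1:**
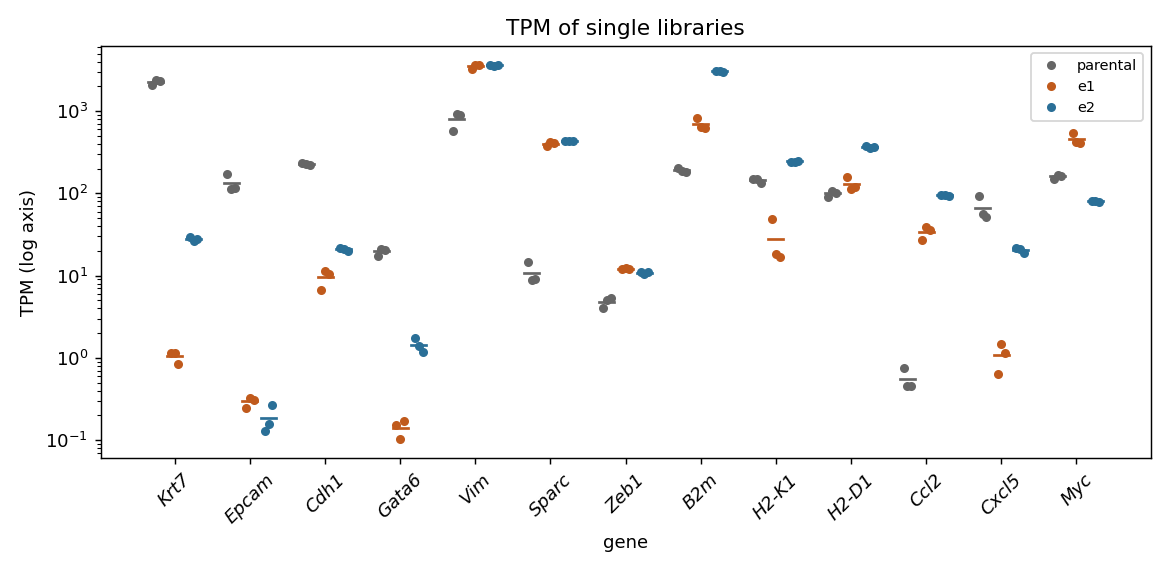
TPM of 13 named genes in each library on a log axis, with parental cells in grey, e1 in orange and e2 in blue; points are libraries and bars the mean of 3. Krt7, Epcam, Cdh1 and Gata6 lie lower in all 6 escape libraries than in parental ones, Vim, Sparc and Zeb1 higher, and H2-K1 lower in e1 alone.

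The comparison of escape e2 with the parental cells asks the same of the second line. The epithelial list was lower and the mesenchymal list higher in e2, with fibroblast marker genes also higher. All 35 epithelial genes were lower, also when adjusted over the list alone (median -3.82, adjusted p = 1.6e-18; adjusted p = 0.0269 with an estimated correlation). Krt7 stood at 28.1 ± 1.79 TPM (-6.28 ± 0.08, adjusted p = 2.45e-11), Epcam at 0.185 ± 0.0737 TPM and Krt19 at 72.2 ± 3.92 TPM against 2059 ± 325 TPM in parental cells. Of 33 mesenchymal genes, 30 were higher and 1 lower, also when adjusted over the list alone (median 2.51, adjusted p = 2.48e-08; adjusted p = 0.0269 with an estimated correlation). Vim rose to 3596 ± 87.4 TPM, Sparc to 431 ± 1.92 TPM, and Prrx1, a transcription factor of mesenchyme, from 0.177 ± 0.022 to 71.4 ± 1.35 TPM. Of 14 fibroblast markers, 12 were higher and 1 lower, also when adjusted over the list alone (median 4.34, adjusted p = 1.28e-05, and 0.0293 with an estimated correlation). As in e1, these counts were largely set by the filter, since all tested markers but Fbln1 entered through escape libraries. Pdpn, the membrane protein podoplanin, rose from 0.0722 ± 0.0562 to 70.3 ± 0.562 TPM, and Dcn, listed at 0 in all 3 parental libraries, stood at 36.3, 35.5 and 34.6 TPM. In the matrix list 22 of 31 genes were higher and 5 lower, also when adjusted over the list alone (median 2.16, adjusted p = 0.00106; adjusted p = 0.184 with an estimated correlation). Mesenchymal and matrix genes near 0 in parental cells, such as Prrx1 and Dcn, could hardly come out lower. Spp1, the secreted protein osteopontin, rose from 1756 ± 453 to 18582 ± 311 TPM.

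Classical subtype genes fell in e2, with 19 of 21 lower and 2 higher, also when adjusted over the list alone (median -2.71, adjusted p = 1.23e-07; adjusted p = 0.0269 with an estimated correlation). Gata6 stood at 1.45 ± 0.295 TPM, and Sox9 rose by 2.62 ± 0.18. The basal-like list did not pass (10 of 17 lower and 4 higher, 11 and 4 adjusted over the list alone; median -0.75, adjusted p = 0.0672), but passed with the 10 highest genes removed (0.0435; 0.0435 to 0.127 over the alternatives). Among the highest fold changes of all genes were Ifitm3, at 9.57 ± 0.10, Grem1, a secreted BMP antagonist, at 8.84 ± 0.08, and Cck, the hormone cholecystokinin, which rose from 0.838 ± 0.362 to 314 ± 11.6 TPM. Gpnmb, a membrane glycoprotein, rose by 7.03 ± 0.22, and Cd34, a sialomucin of progenitor cells, by 6.99 ± 0.10.

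Class I presentation genes rose in e2: 19 of 21 were higher and 1 lower, also when adjusted over the list alone (median 1.41, adjusted p = 1.15e-05; adjusted p = 0.164 with an estimated correlation). B2m rose to 3062 ± 55.7 TPM (3.99 ± 0.10, adjusted p = 8.31e-10), H2-D1 to 367 ± 8.1 TPM (1.86 ± 0.11), Tap1 by 2.93 ± 0.14, Psmb8 by 4.25 ± 0.36 and Nlrc5, the activator of class I genes, by 2.67 ± 0.10. H2-Q7 on chromosome 17 (35439140 to 35443773), a nonclassical class I gene with close copies, rose by 4.19 ± 0.10. H2-K1 stood at 245 ± 4.34 TPM against 145 ± 8.27 TPM and did not pass (0.76 ± 0.34, adjusted p = 0.0802). It passed without e1 library 1 (adjusted p = 4.95e-07) and with 2 groups only (adjusted p = 1.93e-06). Over all alternatives that p ran from 4.95e-07 to 0.163.

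Of 34 type I interferon genes, 28 were higher and 2 lower in e2, also when adjusted over the list alone (median 1.93, adjusted p = 1.28e-05; adjusted p = 0.534 with an estimated correlation). Among them were Isg15 at 3.98 ± 0.28, Oasl2, of the oligoadenylate synthetase family with close copies, at 4.21 ± 0.24, and Zbp1, a sensor of Z-form nucleic acid, at 4.17 ± 0.19. Of 22 interferon gamma genes, 18 were higher and 2 lower, also when adjusted over the list alone (median 1.28, adjusted p = 0.00106; adjusted p = 0.164 with an estimated correlation). Gbp2, a guanylate-binding protein of a family with close copies, rose by 3.39 ± 0.09, while Ifngr1 fell by 1.09 ± 0.07 and Jak2 by 0.60 ± 0.11. The checkpoint list did not pass (6 of 16 higher and 9 lower, also when adjusted over the list alone; median -0.60, adjusted p = 0.233). Cd47 rose from 53.7 ± 3.75 to 135 ± 3.23 TPM. Cd274 passed at 0.28 ± 0.11 (adjusted p = 0.0365). That call was lost with median-ratio scaling (0.0908), a pseudocount of 0.1 (0.0928) and the rlog values (0.144). It was also lost without parental library 1 or 2, without e1 library 3 and without each e2 library in turn, with adjusted p from 0.0501 to 0.105 there and from 0.018 to 0.144 over all alternatives. Ccl2 rose by 5.96 ± 0.13, Ccl7, another monocyte chemoattractant, by 4.85 ± 0.22, and Vcam1, an adhesion ligand of lymphocytes, by 3.33 ± 0.11. The granulocyte factor gene Csf3 fell by 2.51 ± 0.17, Cxcl5 by 1.62 ± 0.22 and Icam1 by 2.42 ± 0.10, and Csf2 did not pass (-0.11 ± 0.10, adjusted p = 0.356).

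Genes of MYC activity and ribosome biogenesis fell in e2, with 23 of 26 lower and 0 higher, also when adjusted over the list alone (median -0.70, adjusted p = 0.000111; adjusted p = 0.659 with an estimated correlation). Myc fell from 161 ± 10.2 to 80.3 ± 1.38 TPM, Nolc1, a nucleolar chaperone, by 1.18 ± 0.17 and Polr1b, a subunit of RNA polymerase I, by 1.07 ± 0.15. Cholesterol synthesis genes fell too, with 21 of 23 lower and 0 higher, also when adjusted over the list alone (median -0.84, adjusted p = 1.45e-06; adjusted p = 0.534 with an estimated correlation). The sterol reductase gene Tm7sf2 fell by 2.18 ± 0.10. Oxidative phosphorylation genes did not pass as a list (17 of 30 higher and 3 lower, also when adjusted over the list alone; median 0.31, adjusted p = 0.0803), but passed under 2 of 18 alternatives (0.0246 to 0.182). Nor did cell cycle genes (15 of 34 higher and 7 lower, 14 and 7 adjusted over the list alone; adjusted p = 0.408) pass. Mki67 rose by 0.48 ± 0.06, Cdkn2a by 0.67 ± 0.05 and Fas by 2.82 ± 0.17, and Trp53, at 0.02 ± 0.07, did not pass (adjusted p = 0.843).

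In all, 9383 genes passed in e2 (9644 at an unadjusted p), 5209 higher and 4174 lower, of which 1752 and 1273 changed by at least 1 on the log2 scale. The balance turned with scaling: 55.5% of these calls were higher, against 49.0% with median-ratio scaling and 49.0% with the rlog values, where the median of all genes moved from 0.07 to -0.01. The libraries did not overlap in 81.4% of genes, where chance gives 10%. Of 30 lists, 10 were called, 6 up and 4 down, and 4 held with an estimated correlation.

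**Figure D2:**
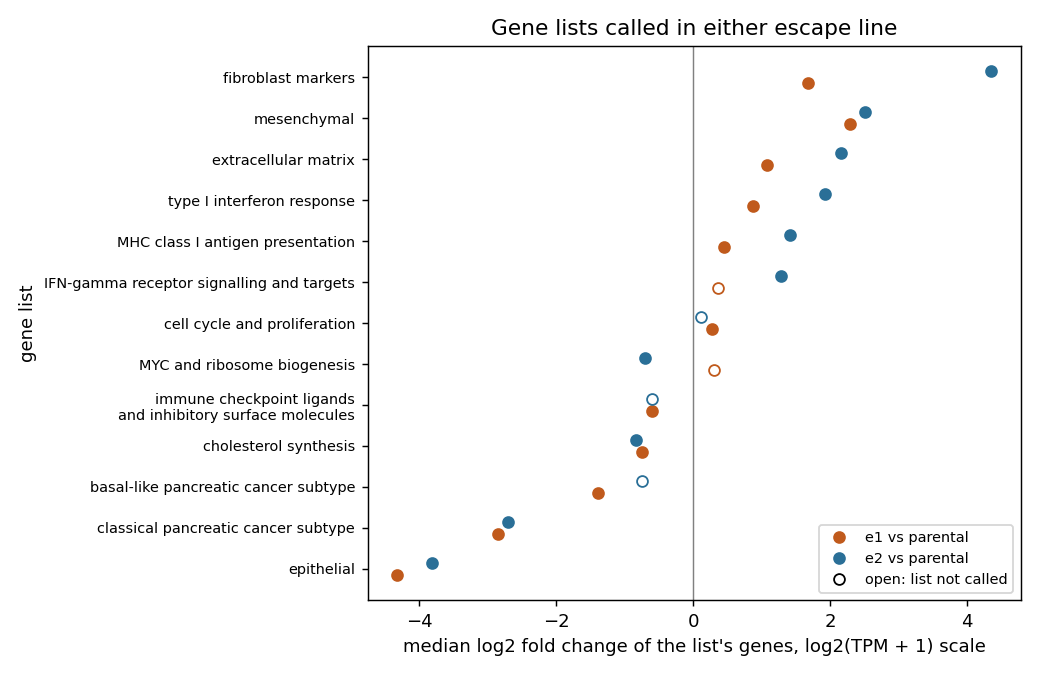
Median log2 fold change against parental cells of each gene list called in either line, e1 in orange and e2 in blue, filled where the list passed and open where it did not. Epithelial genes lie at -4.32 in e1 and -3.82 in e2, and fibroblast markers at 1.68 in e1 and 4.34 in e2.

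The comparison of e2 with e1 asks how the lines differ from each other. Serpine2, a serine protease inhibitor, stood at 1.61 ± 0.243 TPM in e1 and 291 ± 6.41 TPM in e2 (6.81 ± 0.14, adjusted p = 6.89e-10). Cck stood at 0.839 ± 0.526 and 314 ± 11.6 TPM, and Pdpn at 0.0518 ± 0.00931 and 70.3 ± 0.562 TPM. Aqp8, a water channel, differed by 6.28 ± 0.07, Mgst1, a glutathione transferase of membranes, by 6.24 ± 0.38, Hhip, a hedgehog-binding protein, by 5.62 ± 0.07, and Prl2c2, of a prolactin family with near-identical copies, by 6.38 ± 0.49. In the other direction, the junction gene Jam3 stood at 33.8 ± 3.27 TPM in e1 and 0.505 ± 0.116 TPM in e2 (-4.53 ± 0.10). Lower in e2 were also the guidance receptor gene Robo1 at -4.36 ± 0.07, the growth factor gene Igf2 at -4.23 ± 0.08, Crabp2 at -4.27 ± 0.18 and the Wnt receptor gene Ror2 at -3.99 ± 0.13.

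The MYC and ribosome biogenesis list was lower in e2 than in e1, with 23 of 26 genes lower and 1 higher, also when adjusted over the list alone (median -1.01, adjusted p = 7.61e-07; adjusted p = 0.618 with an estimated correlation). Myc itself differed by -2.49 ± 0.10, and in 25 of the 26 genes e1 library 1 lay above both other e1 libraries. Class I presentation genes were higher in e2, 15 of 21 higher and 2 lower, also when adjusted over the list alone (median 1.03, adjusted p = 0.0284; adjusted p = 0.563 with an estimated correlation). H2-K1 differed by 3.25 ± 0.34 and B2m by 2.14 ± 0.10. Chromatin regulators were lower, 17 of 26 lower and 5 higher, also when adjusted over the list alone (median -0.31, adjusted p = 0.0284; adjusted p = 0.563 with an estimated correlation). They included the histone methyltransferase gene Setdb1 at -0.79 ± 0.07 and the DNA methyltransferase gene Dnmt1 at -0.54 ± 0.05. The type I interferon list (23 of 34 higher and 3 lower, also when adjusted over the list alone) missed the threshold at an adjusted p of 0.0523, and cell cycle genes (9 of 34 higher and 19 lower, also when adjusted over the list alone) at 0.0523. Each of these 2 lists passed under 9 of 18 alternatives, among them median-ratio scaling, the rlog values and leaving out e1 library 1. Their adjusted p ran from 0.00104 to 0.0681 and from 0.0158 to 0.0659. NF-kB targets (14 of 22 higher and 4 lower, also when adjusted over the list alone) missed it at 0.0534 and passed under 10 of 18 alternatives (0.0218 to 0.064). A further 7 lists passed under 2 to 5 alternatives. In all, 8981 genes passed (9266 at an unadjusted p), 5189 higher and 3792 lower in e2, 1677 and 597 of them by at least 1 on the log2 scale, and libraries did not overlap in 76.5% of genes where chance gives 10%. The share of higher calls, 57.8%, depends on scaling: it was 51.9% with median-ratio scaling, 51.0% with the rlog values and 61.3% with the 10 highest genes removed. Of 30 lists, 3 were called and 0 held with an estimated correlation. The number called moved between 3 and 11 when single libraries were left out, to 11 without parental library 1, 6 without parental library 3, 9 without e1 library 1 and 6 without e2 library 1.

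The changes of the lines were also set side by side. In both lines 5496 genes passed in the same direction, 2905 higher and 2591 lower, against 1860 and 1456 for independent lists and a median of 0 for simulated unchanged lines that share the parental libraries (100 simulations). In opposite directions 1472 passed. Among genes changed by at least 1 on the log2 scale in each, 629 were higher in both, 940 lower in both and 49 opposite. The last group included Aqp8, at -3.22 ± 0.07 in e1 and 3.06 ± 0.07 in e2, and Mgst1, at -3.23 ± 0.38 and 3.01 ± 0.38. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.73 and a Spearman rho of 0.57, against a simulated r of 0.50 from the shared parental libraries. Their covariance was 1.04 against 0.0143, a difference of 1.03. With 3 parental libraries no split leaves 2 in each part, so part of the excess of the counts over independent lists may come from the shared controls. The difference in covariance leaves out only the noise of those libraries, not features of the parental cells themselves. The simulation took both lines as unchanged, whereas most tested genes passed in each, so its median of 0 is no yardstick for the count. With the e2 libraries in the parental place 5292 genes passed alike, so a count near 5496 does not need parental cells as the reference. For the mean of both lines against parental cells 9252 genes passed (9496 at an unadjusted p), 5033 higher and 4219 lower, and of 30 lists 10 were called, 6 up and 4 down, 4 of them with an estimated correlation.

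**Figure D3:**
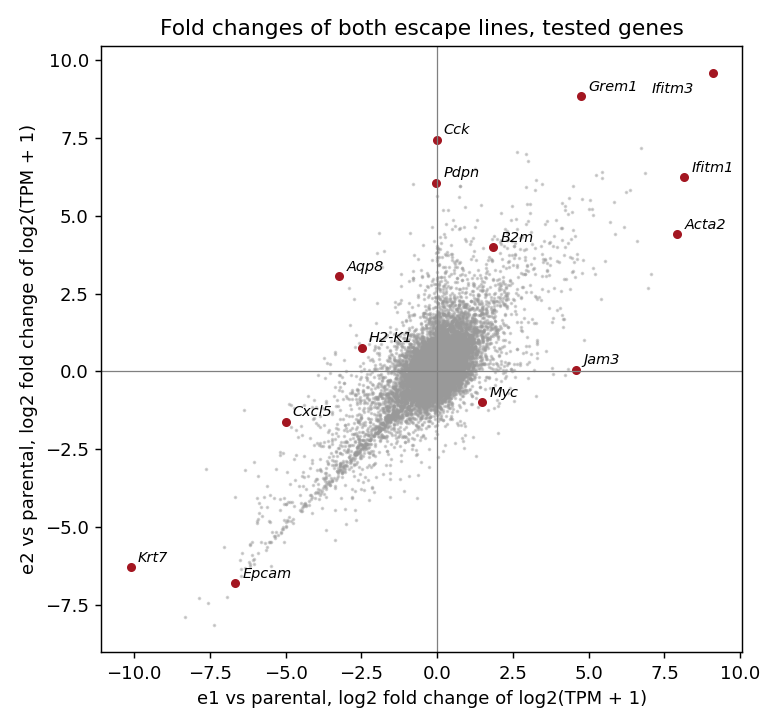
Log2 fold change against parental cells of each tested gene in e1 (horizontal axis) and e2 (vertical axis) on the log2(TPM + 1) scale; grey points are genes, red points named ones. Krt7 and Epcam lie far below 0 and Ifitm3 far above 0 in both lines, while Cck and Pdpn lie high in e2 and near 0 in e1, and Jam3 the reverse.

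Few markers of other cell types outside the fibroblast list reached 1 TPM, though some of them rose. By group mean, 1 of 20 leukocyte markers stood at 1 TPM or more in parental cells, 2 in e1 and 3 in e2. S100a8, a calcium-binding protein of neutrophils, rose in e2 from 0.576 ± 0.476 to 7.62 ± 2.27 TPM. Of 11 endothelial markers 1, 2 and 2 did. Flt1, a growth factor receptor, rose from 1.65 ± 0.435 to 10.2 ± 2.29 TPM in e1 and 23.6 ± 0.61 TPM in e2. Of 14 acinar markers 1, 1 and 1 did, and this was Cela1, an elastase, which rose from 2.02 ± 1.25 to 7.89 ± 2.16 TPM in e1 and 16.1 ± 1.02 TPM in e2. Of 14 endocrine and neuronal markers 0, 1 and 1 reached that level, and Isl1, a transcription factor of islets, rose in e2 from 0.0164 ± 0.0142 to 5.39 ± 0.493 TPM. Xist, the RNA of X inactivation, stood at 34 ± 2.68, 19.9 ± 1.83 and 21.2 ± 0.517 TPM in parental cells, e1 and e2.

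Fold changes were also summarised by chromosome, a step chosen after the data were seen. Whole chromosomes shifted: the median log2 fold change of genes on chromosome 5 lay -0.58 from that of all genes in e1 and -0.05 in e2, and of chromosome 16 -0.03 in e1 and -0.72 in e2. Chromosome 13 shifted up in both lines, by 0.50 and 0.68, and chromosomes 17 and 19 down, by -0.38 and -0.41 in e1 and by -0.32 and -0.34 in e2. By a limit of 0.3 and beyond all 10000 random gene sets matched on expression, 8 of 20 chromosomes shifted in e1 (1, 3, 5, 12, 13, 14, 17 and 19) and 4 in e2 (13, 16, 17 and 19). Named genes on shifted chromosomes include H2-K1, H2-D1 and H2-Q7 on chromosome 17. These genes did not follow its downward shift. H2-D1 lay at 0.36 in e1, and H2-Q7 at 4.19 and H2-K1 at 0.76 in e2, while H2-K1 in e1 fell by more than the shift.

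**Figure D4:**
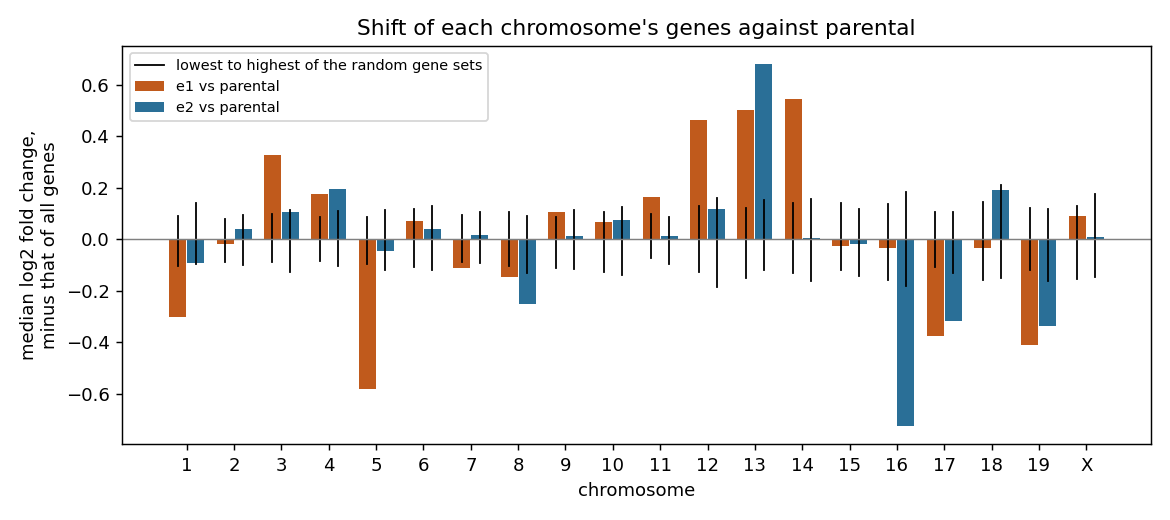
Shift of each chromosome's genes against parental cells, as the median log2 fold change minus that of all tested genes, for e1 (orange) and e2 (blue); black lines span the lowest to highest of the random gene sets of the same size. Chromosome 5 reaches -0.58 in e1 alone, chromosome 16 reaches -0.72 in e2 alone and chromosome 13 lies above 0 in both.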

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

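The tests of the epithelial pattern, with their limits, were chosen after its result was seen, as was the bootstrap interval for e1 library 1, while the other limits were set before their values. An earlier criterion for fibroblasts in place of tumor cells, that the markers Dcn and Lum reach 1 TPM, was replaced by a limit on Pdx1 after the values of all 3 genes were seen, because Lum was listed at 0 in all 9 libraries. Under it Lum alone would have spoken against fibroblasts in e2, where Dcn stood at 36.3, 35.5 and 34.6 TPM. Of 102 tested genes named in the text, 80 differed between e2 and e1, and each is listed because the effects of the lines against parental cells differ by the test of e2 minus e1. In all 8981 genes, 70.3% of those tested, and 3 lists differed in that test. The naming rule takes genes partly by their change between e2 and e1, so the count of 80 is in part set by selection. Of the named genes, 9 were called in opposite directions against parental cells. Among these, S100a8 passed in e1 at an adjusted p of 0.0345 and not with no filter, the rlog values, without parental library 1 or without any single e1 library.

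By log2 fold change of e2 minus e1, genes above 5 were Cck (7.46), Serpine2 (6.81), Prl2c2 (6.38), Aqp8 (6.28), Mgst1 (6.24), Pdpn (6.08), Hhip (5.62) and Prrx1 (5.18). Next came Dcn (4.99), Gpnmb (4.39), H2-Q7 (4.29), Grem1 (4.10), Cd34 (4.06), Krt7 (3.83), Spp1 (3.38), Cxcl5 (3.38), H2-K1 (3.25), Csf2 (3.11), S100a8 (3.07) and Zbp1 (3.06). Interferon and presentation genes followed with Psmb8 (2.45), Nlrc5 (2.36), B2m (2.14), Tap1 (2.10), Oasl2 (1.90), Jak2 (1.84), H2-D1 (1.5) and Gbp2 (0.41). Surface, death and chemokine genes were Fas (1.80), Cd24a (1.78), Cd47 (1.53), Bcl2l1 (1.51), Ccl2 (1.47), Vcam1 (1.06), Casp8 (1.05), Cd274 (0.96), Ccl7 (0.94) and Raet1d (0.62). Epithelial, matrix and other genes were Isl1 (2.46), Muc1 (1.40), Insig1 (1.27), Sox9 (1.20), Flt1 (1.16), Gata6 (1.09), Cdh1 (1.09), Cela1 (0.97), Ifitm2 (0.81), Pdx1 (0.67), Ifitm3 (0.46), Mgp (0.44), Mki67 (0.42) and Tm7sf2 (0.39).

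Lower in e2 were Jam3 (-4.53), Robo1 (-4.36), Crabp2 (-4.27), Igf2 (-4.23), Ror2 (-3.99), Fstl1 (-3.92), Acta2 (-3.52), Myc (-2.49), Ifitm1 (-1.92), Ifitm10 (-1.78), Thbs1 (-1.66), Col1a1 (-1.52) and Polr1b (-1.44). Smaller differences were Ccl5 (-1.29), Nolc1 (-1.18), Jup (-0.98), Cxcl10 (-0.87), Trp53 (-0.85), Setdb1 (-0.79), Usp22 (-0.70), Serpinb9 (-0.68), Psme2 (-0.57), Mb21d1 (-0.56), Dnmt1 (-0.54), Col1a2 (-0.49), Irf1 (-0.45), Cldn7 (-0.31) and Cdkn2a (-0.22). The call of Cxcl10 ended with 2 groups only, without parental library 2 and without each e2 library, and its value was -0.45 without e1 library 1. The call of Serpinb9 ended with 2 groups only and without e1 library 2 (-0.51), e1 library 3 (-0.53) and e2 library 2 (-0.62).

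The loss of epithelial and gain of mesenchymal expression was weighed against admixture. Unchanged parental-type cells diluted by fibroblasts would leave epithelial genes and Pdx1, a pancreatic transcription factor that fibroblasts lack, at a like share of their parental TPM, but Pdx1 kept at least 43.3 times the median share of 30 epithelial genes in e1 and 31.4 times in e2. Fibroblasts in place of tumor cells would bring their markers and lose Pdx1. In all e1 libraries 9 of 16 markers were at 1 TPM or more, against 1 of 16 by mean in parental cells. That is fewer than a limit of 13 chosen after the values were seen, so the marker count cannot argue against fibroblasts in e1. In e2 13 markers reached that level. Only Pdx1, which kept at least 32.5% of its parental TPM in e1 and 57.4% in e2, speaks against them, by a limit also chosen afterwards. A change of state within the tumor cells may account for the pattern, as a hypothesis found and tested on the same data. Another pancreatic line or an exchanged label stays open, because no genotype was measured.

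Escape e1 library 1 lay apart from e1 libraries 2 and 3, with 222 genes more than 1 log2 from their mean against 94 between libraries 2 and 3, with lists moving both ways. Type I interferon genes lay above both other libraries in 28 of 34 cases, cholesterol in 22 of 23, MYC in 25 of 26, unfolded protein response in 22 of 28 and RAS/MAPK in 21 of 26, while oxidative phosphorylation genes lay below both in 26 of 30 and NRF2 in 18 of 22. Mixing with parental cells was argued against by a median excess of -0.0332% of the parental TPM over 38 genes that e1 lacks. Mixing with e2 (0.0247% over 5 genes) cannot be told apart from none, as the genes are too few. GC content and transcript length explained 4.83% of the variance, with a bootstrap interval from 4.10 to 6.16%, which argues against them as the source of most of the deviation. The interval lies across the 5% limit set before, so a small part from this source stays open. No biological explanation was tested.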

How the results depend on the processing

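All leave-one-out and setting changes here were planned, and the list of settings was fixed before the data were examined. Counts of called genes stayed within 1.5 times of the reported value under each alternative: 7548 to 10152 for e1 against parental, 7795 to 10908 for e2 against parental, 7630 to 10038 for e2 against e1, 7650 to 10778 for the mean and 4548 to 6385 for genes changed alike, with r between 0.72 and 0.75. Lists called for e2 against e1 numbered 5 with a pseudocount of 0.1, 11 with no filter, 5 with a filter of 5 TPM, 7 with median-ratio scaling, 8 with the rlog table, 12 with 2 groups only and 3 to 11 when single libraries were left out, and the cause was not tested. With an estimated correlation 3 lists were called for e1, 4 for e2 and 0 for e2 against e1. That alternative also changes the form of the test, and the effects were not separated. In these 3 comparisons each list called with the preset correlation passed in the same direction under the 18 other alternatives; the lists of the mean were not run under them.

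Of 306 values of named genes, 62 moved by over 1.5 times or changed their call with a pseudocount of 0.1, 25 with the rlog table and 18 without e1 library 1. Without that library 3 turned direction: Nolc1 in e1 to -0.23 (0.12 without e1 library 2), Pvr in e1 to -0.21 (0.39 without e1 library 2), and Isg15 in e2 against e1 to 0.17 (-0.44 without e1 library 2). None of them had passed before, and the cause was not tested. Scaling moved the share of higher calls by less than 10 points and the median of all genes by less than 0.1. The library numbers did not pair the samples: deviations of same-numbered libraries correlated between -0.13 and 0.05 over 9 pairs, and as a block the number gave 8742, 9163 and 8740 called genes for the 3 comparisons in the order above. Read depth is unknown, so low values cannot be given a limit.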

Other observations

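The gene families here and the chromosome summaries were chosen after the data were seen, while the limits of the chromosome tests and the counts of splits were set before their results. The p-values of the families come from the data that led to their choice. They describe the families and are no independent test, and the adjustment over 8 families does not cover the choice. Cytosolic ribosomal protein genes were lower in e2 than in parental cells, with 73 of 80 lower and 3 higher (median -0.41, adjusted p = 2.99e-12 over 8 families; adjusted p = 0.416 with an estimated correlation), and took 16.3 to 16.7% of TPM in e2 against 21.0 to 21.7% in parental cells. They were lower than in e1 too (11 higher and 62 lower, adjusted p = 4.06e-11; adjusted p = 0.350 with an estimated correlation), while between e1 and parental cells the family did not pass (28 higher and 28 lower, adjusted p = 0.823). Under each scaling the median in e2 against parental cells stayed below 0, between -0.50 and -0.37. The filter admitted some Hox genes only through e1, so this family is given with no filter, an alternative chosen after seeing the data. Of 36 Hox genes, 15 were higher and 2 lower in e1 (adjusted p = 0.00829; adjusted p = 0.479 with an estimated correlation), and 7 were higher and 17 lower in e2 than in e1 (median -0.08, mean -0.64, adjusted p = 0.00429; adjusted p = 0.289 with an estimated correlation). Between e2 and parental cells the family did not pass (9 higher and 11 lower, adjusted p = 0.512), with a median of 0.02 and a mean of -0.30. With the filter it did pass there: of 11 Hox genes 1 was higher and 9 lower in e2 (median -1.11, adjusted p = 0.0140, and 0.445 with an estimated correlation). The result for e2 against parental cells thus depends on the filter. Replication-dependent histone genes were higher in both lines, 37 of 53 in e1 (adjusted p = 0.000118; adjusted p = 0.436 with an estimated correlation) and 33 of 53 in e2 (adjusted p = 0.00329; adjusted p = 0.416 with an estimated correlation), though near-identical copies make single members uncertain. With no filter the calls of ribosomal protein genes in e2 (2.37e-12) and of histones (1.36e-05 and 0.00223) stayed. Proteasome subunit genes were higher in e1, 24 of 41 higher and 7 lower (adjusted p = 0.0206; adjusted p = 0.749 with an estimated correlation), and lower in e2 than in e1, 7 higher and 27 lower (adjusted p = 4.63e-05; adjusted p = 0.387 with an estimated correlation), but did not pass between e2 and parental cells (9 and 20, adjusted p = 0.116). This family was taken by gene name and left out Psmb8, Psmb9 and Psmb10. It held Psmc3ip, which is not a subunit, and Psme1 and Psme2, which are also in the class I list. Of 12 cathepsin genes 10 were higher and 1 lower in e2 than in e1 (adjusted p = 0.0085; adjusted p = 0.350 with an estimated correlation), and against parental cells they did not pass (0.554 in e1 and 0.245 in e2). With no filter these calls stayed (0.00393, 3.99e-06 and 0.0072). All 3 tested Prl2c and placental lactogen genes were higher in e2 than in e1, among them Prl2c2, already named for its large difference. The test of this family, also below 5 genes, restates that (adjusted p = 0.0355, and 0.350 with an estimated correlation). With no filter the family did not pass (0.171), nor did it against parental cells (0.249 in e1 and 0.0823 in e2). Glutathione S-transferases did not pass in any comparison (0.622, 0.0836 and 0.0946), nor did histones between e2 and e1 (0.367). The 4 tested Ifitm genes, fewer than the 5 asked of the lists, include Ifitm3 and Ifitm1, already among the highest fold changes. Their family test therefore restates those values. Its adjusted p was 0.00289 in e1 (0.436 with an estimated correlation), 0.0140 in e2 (0.416 with an estimated correlation) and 0.501 between e2 and e1. Each of the 4 rose in e1. In e2 Ifitm1, Ifitm2 and Ifitm3 rose, while Ifitm10 passed at an adjusted p of 0.048 and not with median-ratio scaling or the rlog values, where 3 of 4 were higher. The call of Ifitm10 was also lost with no filter and with the library number as a block. It was lost too without any single parental library, without e1 library 2 and without e2 library 1 or 2. In these further fits its adjusted p ran from 0.0504 to 0.158.

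Whole-chromosome shifts were the third pattern weighed. A trend with GC content and transcript length was argued against, since its removal left chromosome 5 at -0.58 in e1 and chromosome 16 at -0.73 in e2, and so was a single cluster of regulated genes, since the least shifted of 5 equal parts of each still lay at -0.47 and -0.61. Gains and losses of chromosome copies in the lines may account for the shifts, as a hypothesis that no DNA measurement here tests. On chromosome 1 parts 1 and 2 of 5 lay at -0.56 and -0.60 in e1 and at 0.34 and 0.24 in e2, so that shift covers part of a chromosome.

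Other splits of the libraries were counted beside each result. Each pair of groups has 10 splits, too few for a share under 0.05. The real split gave 9014, 9383 and 8981 genes and the highest other 1, 1 and 2, so that 1 split each was as large; for lists the real values were 11, 10 and 3, the highest others 9, 12 and 8, and the splits as large 1, 7 and 8. For the mean of both lines, 2 of 100 drawn splits called as many genes as the real 9252, the highest 9490, which is the split that puts the e2 libraries in the place of parental cells and so points to the structure of the 3 lines. An earlier draw of the same number held no such split, and this one is reported. For genes changed alike 1 of 100 reached 5496, the highest other being 5292 from that same split. Both counts show that libraries of a group resemble each other, which 3 distinct lines give whatever separates them. Whether libraries of a group are separate cultures is unknown, so the splits do not exclude chance differences between cultures. For r, 46 of 100 splits reached 0.73 (highest other 0.954). Splits that mix lines in the shared group carry line differences into both fold changes and raise r by construction, so this count does not test r. Its no-change value is the simulated 0.50 given in the report.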
